A study of Mus musculus with 20 samples.

How the data were processed

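The series holds 20 samples in 8 groups, taken from the sample titles. Per the labels' protocols, EYFP-positive 5-HT neurons were sorted by flow cytometry, and their RNA was amplified with the Clontech SMARTer kit (E11.5, E15.5 and postnatal wild type, E15.5 knockout) or with the NuGEN Ovation kit (E15.5 wild type and knockout), in 3 libraries per group. Chromatin from embryonic hindbrain was precipitated with an antibody against the Myc tag, as 1 sample with 1 input. For that sample the labels conflict, giving wild type in one field and a Pet-1 knockout with the tagged transgene in another, and E14.5 or E15.5 as the last age. The sources used here do not say that replicates came from separate animals. The p-values of the stage tests and the authors' deposited p and q therefore rest only on these samples, whose spread may be technical. Fisher's exact tests were computed across genes taken as independent, so their p-values measure no spread between samples.

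The submitters' processing notes name TopHat2, Cufflinks and BWA without versions, MACS 1.4.2, and the builds mm9 and mm10 with no role. FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) were deposited by the authors per library for the stages and per group for the knockout, in tables of Cuffdiff form per the file headers. The log2 fold changes of the authors' deposited tables are ratios of group FPKM, infinite where a group is 0. Per the file headers the authors' deposited tables also hold a p-value and a q-value per gene. The peak list was deposited by the authors for mm10 with a score per peak, and its track line names MACS. Loci in the expression tables are not mm10 coordinates and were not used. Whether the authors rescaled FPKM between libraries is not given in the sources used here. The knockout tables of the kits were normalised separately, and levels were not tested across them.

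The stage matrix held 22556 genes, and 25 rows had names turned into dates, which were not renamed. Its columns name a stage but no replicate of the labels, so libraries were letters a to c in column order. Another 3 columns matched no sample and were not used. The E15.5 columns name no kit. Their group FPKM lay close to the Clontech wild type (median ratio 0.987, with 5% to 95% of 6473 genes between 0.839 and 1.14), and less close to the Clontech knockout (0.582 to 1.39) and the NuGEN wild type (0.435 to 2.04), and the protocol gives Clontech for this series. Genes with a failed estimate, 14 in all, were listed at 0 in some libraries although every cell uses some of them, such as Actb and Stmn1, and were left out. Depth is unknown, since the files give no read numbers, so no counting error could be given. Pearson correlations of log2 values were 0.903 to 0.966 within groups and 0.794 to 0.888 between groups, so no library was a copy of another.

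Stage changes were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), a scale that understates the change of low genes, with a mean-variance trend and 1 fit over the 9 wild-type libraries (6 residual degrees of freedom). Genes with at least 1 FPKM in at least 3 libraries were tested (11741), and called at a Benjamini-Hochberg adjusted p below 0.05 and at least 1.5-fold. The difference between the later and the earlier interval was tested in the same fit. The 23 gene lists were tested with camera at a preset correlation of 0.01, two-sided, adjusted over 69 tests of lists and comparisons, and over the 23 lists of a comparison when counted over splits of the libraries. Lists covered serotonin synthesis and transport, serotonin neuron transcription factors, receptors, channels, synaptic release, axon guidance, cell cycle, progenitors, Hox genes, neuropeptides, immediate early genes, oxidative phosphorylation and markers of other cells, and no gene stood in more than 1 list. The limma step was tested on simulated data with 11741 genes. It recovered 56.1% of genes changed 4-fold and 2.70% of those changed 2-fold for E11.5 to E15.5, 57.3% and 1.96% for E15.5 to PN, and 49.4% and 5.48% for E11.5 to PN, with 0 of those changed 1.5-fold and 2, 0 and 2 false calls. Far fewer genes were changed in the simulation (60, 74 and 66 at 1.5-, 2- and 4-fold for E11.5 to E15.5) than were called in the data (3394). The adjusted threshold was therefore stricter in the simulation, and these shares do not give the power of the real comparisons. How often modest changes were missed is not known.

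Knockout calls used the q-value of the authors' deposited tables (below 0.05), at least 1.5-fold and at least 1 FPKM in a group, with no test on libraries. Overlaps, lists and links to the stages were tested with Fisher's exact test, two-sided, and list medians were set against 10000 random lists matched on FPKM in 10 bins. The link to the stages used the NuGEN table, because the Clontech table shares its wild-type libraries with the stage series. Peaks were matched to genes by RefSeq's GRCm38.p6 gene spans, where 10420 of 10501 genes (99.2%) were found, 9352 by symbol and 1068 by synonym. Those spans carry no strand, so a peak within 5 kb of either gene end was counted in place of the planned distance to a transcription start. These steps were tested on simulated data, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

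Genes were named by a rule. For the stages it took the 6 largest rises and 6 largest falls per interval among called genes whose libraries did not overlap, members of the 3 serotonin lists with at least 1 FPKM in a stage, and 2 called members each way from every other list. For the knockout it took the 10 lower and 10 higher genes by mean log2 change among those called in both kits, the same 3 lists, and 2 members each way per other list. For peaks it took the 5 highest scores and those near members of the 3 lists. Fev was always named, and predicted or unnamed genes were skipped in the top lists. Genes named outside the rule are marked in the text, apart from those of the figures.

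Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, upper quartile scaling, limma without the trend, at least 2-fold, the authors' deposited q, leaving out each library, camera with an estimated correlation, fry, other thresholds or 1 kit for the knockout, and 1 or 20 kb, the higher-scoring peaks or 1 kit for peaks. Calls were also counted over 10 splits of the libraries per pair of stages and 100 for the difference.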

Results

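The series profiled messenger RNA of serotonin (5-HT) neurons of C57BL/6 mice and mapped where a Myc-tagged form of the transcription factor Pet-1, encoded by Fev, sat on chromatin. Pet-1 belongs to the ETS family and in the brain is largely restricted to 5-HT neurons. Neurons marked by the yellow fluorescent protein EYFP were sorted by flow cytometry, and their RNA was amplified with a Clontech or a NuGEN kit. Of the 20 samples in 8 groups, 9 were wild-type Clontech libraries, 3 each from E11.5, E15.5 (E for embryonic day) and postnatal days 1 to 3 (PN). At E15.5 a further 3 Pet-1 knockout libraries were made with the Clontech kit, and 3 wild-type and 3 knockout libraries with the NuGEN kit. The remaining samples were 1 chromatin immunoprecipitation from embryonic hindbrain and 1 input. Read numbers per library were not given in the files used here, so depth is unknown. FPKM values of the 9 stage libraries summed to between 630091 and 919994, and 9614 to 11280 genes per library reached 1 FPKM. Across 11741 genes tested, the first principal component took 40.6% of the variance and parted E11.5 from the later libraries. The second took 27.6% and parted E15.5 from PN.

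The stage series asks how the transcriptome of these neurons changes as they mature. Between E11.5 and E15.5 Fev, Tph2 and Slc6a4 fell in the libraries of sorted neurons, and Pcp4 and Sst were among the genes that rose. Fev fell from 266 ± 112 to 35.2 ± 20.5 FPKM (mean ± SD, n = 3). This was a log2 change of -2.99 (SE 0.49, limma, adjusted p = 0.00104). Tph2, the rate-limiting enzyme of serotonin synthesis in the brain, fell from 188 ± 103 to 64.1 ± 12.6 FPKM (n = 3, log2 change -1.43, SE 0.38, limma, adjusted p = 0.0141). Slc6a4, the plasma membrane serotonin transporter, went from 98.2 ± 54.7 to 25.9 ± 2.24 FPKM (n = 3, log2 change -1.76, SE 0.35, limma, adjusted p = 0.00304). Among the steepest rises, Pcp4, a small calmodulin-binding protein, went from 0.565 ± 0.0744 to 301 ± 28.1 FPKM, and the somatostatin gene Sst from 4.85 ± 1.45 to 1010.5 ± 399 FPKM (n = 3 each, log2 changes 7.59 and 7.37, limma, adjusted p = 2.88e-09 and 5.76e-08).

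In the list for serotonin synthesis and transport, 7 of 13 measured genes fell and 0 rose from E11.5 to E15.5, and 8 fell when adjusted over the list alone. Camera called the list lower (adjusted p = 6.36e-04, and adjusted p = 0.295 with an estimated correlation). Besides Tph2 and Slc6a4, the members that fell were Ddc, Qdpr, Spr, Pcbd1 and Slc22a3. Ddc, the decarboxylase that follows Tph2, dropped by 0.86 on the log2 scale (SE 0.24), from 299 ± 42.6 to 164 ± 13.7 FPKM (n = 3). Qdpr, Spr and Pcbd1, which make or recycle the cofactor tetrahydrobiopterin, had log2 changes of -1.08, -1.66 and -1.99. Slc22a3, an organic cation transporter, had one of -3.15. Slc18a2, the vesicular monoamine transporter, was at 34.2 ± 20.1 and 21.3 ± 5.02 FPKM (n = 3) and did not pass the test (limma, adjusted p = 0.298).

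Of 15 transcription factors of serotonin neurons, 8 fell and 0 rose, 10 when adjusted over the list alone (camera adjusted p = 4.58e-05, and adjusted p = 0.183 with an estimated correlation). They were Fev, Lmx1b, Gata2, Nkx2-2, Insm1, Hmx2, Hmx3 and Pou3f2. The zinc finger factor Gata2 fell from 135 ± 42.4 to 34.6 ± 12.6 FPKM, and the LIM homeobox factor Lmx1b from 31.5 ± 19.5 to 6.06 ± 1.10 FPKM (n = 3 each, log2 changes -1.96 and -2.06, limma, adjusted p = 0.00175 and 0.0142). Insm1, expressed in newborn neurons, had a log2 change of -2.36 (SE 0.35). Gata3, at 246 ± 59.0 and 149 ± 27.3 FPKM (n = 3), just missed the threshold (limma, adjusted p = 0.0581).

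Of 17 measured GABA and glycine receptor genes, 10 rose and 0 fell from E11.5 to E15.5, 13 when adjusted over the list alone (camera adjusted p = 4.73e-04, and adjusted p = 0.271 with an estimated correlation). Gabrb2, a GABA-A receptor subunit, rose from 1.65 ± 1.26 to 15.1 ± 5.18 FPKM (n = 3, log2 change 2.69, SE 0.42). Of 18 glutamate receptor genes, 9 rose and 0 fell, 10 when adjusted over the list alone (camera adjusted p = 0.0278, and adjusted p = 0.415 with an estimated correlation), among them the metabotropic receptor Grm8 (log2 change 2.12, SE 0.37). The synaptic vesicle and release list gave 9 genes up and 2 down of 30 (camera adjusted p = 0.0446, and adjusted p = 0.183 with an estimated correlation). Snap25, a SNARE protein of the release machinery, rose from 35.5 ± 17.5 to 274 ± 32.2 FPKM (n = 3). Syt4 rose by 4.58 (log2, SE 0.57), whereas Rims2 and Unc13a, which prime vesicles, fell by 1.47 and 0.96. Among other potassium and HCN channels 6 of 13 rose and 1 fell (camera adjusted p = 0.0424, and adjusted p = 0.199 with an estimated correlation), with Kcnk1 and Kcnk2 up and Kcnn1 down. Neuropeptide genes gave 5 up and 1 down of 14 (camera adjusted p = 0.0416, and adjusted p = 0.273 with an estimated correlation), led by Sst and by the prodynorphin gene Pdyn (log2 change 4.27, SE 0.36), with Adcyap1 down.

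Some markers of other cells rose in the same interval. Of 9 astrocyte markers, 5 rose and 1 fell (camera adjusted p = 0.00761, and adjusted p = 0.365 with an estimated correlation). The glutamate transporter gene Slc1a3 was at 0.00729 ± 0.0126 FPKM at E11.5 and 14.9 ± 7.62 FPKM at E15.5, and Sparcl1 at 1.31 ± 1.16 and 44.0 ± 24.0 FPKM (n = 3). Mbp and Olig1 were among 3 of 4 oligodendrocyte lineage genes that rose, though camera did not call that list (adjusted p = 0.111). For the cell cycle list 10 of 26 genes rose and 3 fell and camera called no direction (adjusted p = 0.211). Rrm2 and Ccnb1 rose while Ccnd2 and Mcm2 fell. The lists for serotonin receptors, other G protein coupled receptors, voltage-gated potassium channels, sodium and calcium channels, axon guidance and growth, neural progenitors, microglia and blood, immediate early genes and mitochondrial oxidative phosphorylation were not called by camera in this interval, with 1, 4, 1, 2, 9, 1, 1, 0 and 6 genes up and 0, 1, 2, 3, 4, 5, 0, 4 and 5 down. In those lists the serotonin-gated channel gene Htr3a rose from 0.133 ± 0.230 to 9.83 ± 2.51 FPKM (n = 3), and the ephrin ligand Efna5 rose from 3.84 ± 1.74 to 22.2 ± 3.09 FPKM (n = 3). The netrin receptor Dcc fell from 9.95 ± 3.12 to 2.70 ± 1.02 FPKM (n = 3). Hox genes and vascular and meningeal markers had 1 measured member each. Markers of glutamate and GABA neurons had 4, and markers of dopamine, noradrenaline and acetylcholine neurons 2. Camera called none of these 4 lists in any interval. Gad1, the GABA-synthesising enzyme, was at 0.00282 ± 0.00488 and 1.62 ± 0.811 FPKM, and Th, which makes the dopamine precursor, at 0.0274 ± 0.0318 and 6.39 ± 2.68 FPKM (n = 3 each, limma, adjusted p = 0.0151 and 0.0148). Adjusted over the list alone, 2 serotonin receptor genes rose, 10 axon guidance genes rose and 4 fell, and 3 progenitor genes rose and 6 fell. On the same basis 7 oxidative phosphorylation genes rose and 6 fell, and 1 dopamine, noradrenaline or acetylcholine marker rose and 1 fell. The remaining lists kept the counts given.

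By limma, 3394 of 11741 genes changed between E11.5 and E15.5, with 2046 higher and 1348 lower at E15.5. Non-overlapping groups of libraries were seen for 42.3% of genes, against 10% by chance for 3 against 3. The median log2 change of all genes was 0.11, and -0.02 once each library was scaled to the same upper quartile, which gave 1659 rises and 1688 falls. The share of rises moved from 60.3% to 49.6% and the balance between rises and falls is not fixed by these data. Other large changes were rises of the transcription factor Nfix (log2 change 7.16), the Ras-like GTPase Rit2 (5.63), Anxa1 (5.56) and Gpx8 (5.39), and falls of Cmtm7 (-6.08), C1ql1 (-5.52), the retinoic acid binding protein Crabp2 (-4.89) and the kinase Mapk12 (-4.43). The multicopy gene Mtrnr2l was listed at 0 in all 3 E15.5 libraries, and Rplp2-ps1 is a pseudogene, so that both are uncertain.

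From E15.5 to the first postnatal days, Slc6a4 rose again, Tac1 and the immediate early gene Fos rose, and Sox11 fell. Slc6a4 went from 25.9 ± 2.24 to 137 ± 29.8 FPKM (n = 3, log2 change 2.35, SE 0.35, limma, adjusted p = 9.80e-04). Tac1, which encodes substance P, rose from 2.33 ± 0.602 to 85.9 ± 32.2 FPKM (n = 3, log2 change 4.66, SE 0.36, limma, adjusted p = 1.07e-05). Sox11, a transcription factor of immature neurons, fell from 289 ± 70.0 to 14.1 ± 2.49 FPKM (n = 3, log2 change -4.25, SE 0.31, limma, adjusted p = 5.67e-06). Fos went from 16.9 ± 1.22 to 148 ± 32.8 FPKM (n = 3, log2 change 3.04, SE 0.57, limma, adjusted p = 0.00367).

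Among serotonin synthesis and transport genes 4 rose and 1 fell of 13 in this later interval, 5 and 1 when adjusted over the list alone, and camera did not call the list (adjusted p = 0.0990). Pcbd1, Spr and Qdpr rose with Slc6a4 (log2 changes 1.47, 1.04 and 1.03), and Maob, a monoamine-degrading enzyme, fell from 34.2 ± 3.29 to 7.52 ± 3.74 FPKM (n = 3). Fev was at 72.3 ± 34.0 FPKM in PN (n = 3), and its change from E15.5 did not pass the test (log2 change 1.07, limma, adjusted p = 0.145). The same was true of Tph2, at 91.5 ± 35.9 FPKM (n = 3, limma, adjusted p = 0.417). Of the transcription factors, Gata2, Gata3 and Insm1 fell further (log2 changes -1.27, -1.01 and -2.06) and Egr1 rose, with no call for the list (camera adjusted p = 0.369). For serotonin receptors there was 1 rise, Htr5b from 0.314 ± 0.275 to 8.68 ± 1.14 FPKM (n = 3), and 1 fall, Htr3a to 0.439 ± 0.481 FPKM (n = 3).

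The synaptic vesicle and release list gave 12 rises and 1 fall of 30 from E15.5 to PN, 13 and 1 when adjusted over the list alone (camera adjusted p = 2.17e-04, and adjusted p = 0.0742 with an estimated correlation). The synapsin genes Syn1 and Syn2 rose to 31.4 ± 6.70 and 29.5 ± 6.32 FPKM (n = 3), and Rab3c fell. Glutamate receptor genes gave 7 rises of 18 and 0 falls (camera adjusted p = 0.00464, and adjusted p = 0.295 with an estimated correlation), including Grin1, the obligatory NMDA receptor subunit, from 1.81 ± 1.35 to 10.5 ± 0.817 FPKM (n = 3), and Grm2. GABA and glycine receptor genes gave 5 of 17 and 0 (camera adjusted p = 0.00724, and adjusted p = 0.363 with an estimated correlation), led by Gabrg3 and Glra3. Sodium and calcium channels had 5 of 19 up and 0 down (camera adjusted p = 0.00724, and adjusted p = 0.259 with an estimated correlation), among them the calcium channel subunits Cacna2d1 and Cacna2d2. Of 13 voltage-gated potassium channels 2 rose, Kcnc4 and Kcnc1, and 0 fell (camera adjusted p = 0.00999, and adjusted p = 0.186 with an estimated correlation). Neuropeptide genes had 6 of 14 up and 0 down, 7 when adjusted over the list alone (camera adjusted p = 0.00105, and adjusted p = 0.170 with an estimated correlation), with Tac1, Sst and Calca as examples. The cell cycle list gave 12 falls of 26 and 0 rises, 14 falls when adjusted over the list alone (camera adjusted p = 4.34e-06, and adjusted p = 0.0827 with an estimated correlation), including Rrm1 (log2 change -2.29) and Ccnb1 (-2.28).

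Of 13 immediate early genes, whose transcripts rise within minutes of stimulation or handling, 12 rose and 0 fell from E15.5 to PN (camera adjusted p = 2.34e-07, and adjusted p = 0.0295 with an estimated correlation, so that the call held). Microglia and blood genes rose in the same libraries, 5 of 8 with 1 fall, Hba-a1 (camera adjusted p = 0.00778, and adjusted p = 0.419 with an estimated correlation). The complement gene C1qc was at 0.155 ± 0.0312 FPKM at E15.5 and 67.7 ± 80.8 FPKM in PN (n = 3). The lipoprotein gene Apoe, an astrocyte and microglia transcript, was at 23.8 ± 18.7 and 2169 ± 2216 FPKM (n = 3), so the SD between PN libraries exceeded the mean for both. Cd68 and the chemokine genes Ccl3 and Ccl4, made by microglia, also rose (log2 changes 4.01, 5.15 and 5.54). Astrocyte genes had 2 of 9 up, Apoe and Aqp4, and were not called as a list (camera adjusted p = 0.271). Camera called no direction for other G protein coupled receptors, other potassium and HCN channels, axon guidance and growth, neural progenitors, the oligodendrocyte lineage or mitochondrial oxidative phosphorylation, with 2, 3, 4, 2, 0 and 5 genes up and 1, 0, 2, 4, 0 and 3 down. Examples from these lists were rises of the adrenergic receptor Adra1b (log2 change 2.08) and the semaphorin Sema6d (1.28), and falls of the ephrin receptor Epha7 (-1.46) and the intermediate filament gene Vim (-1.72). Adjusted over the list alone, rises and falls were 1 and 4 for serotonin neuron transcription factors, 8 and 0 for glutamate receptors, 7 and 0 for GABA and glycine receptors, and 4 and 0 for other potassium and HCN channels. They were 7 and 0 for sodium and calcium channels, 3 and 0 for axon guidance, 3 and 0 for astrocytes, 6 and 1 for microglia and blood, 0 and 1 for vascular markers and 5 and 4 for oxidative phosphorylation. The remaining lists kept the counts given.

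In all, 2370 genes changed from E15.5 to PN by limma, 1249 higher and 1121 lower in PN. Rises and falls numbered 1359 and 976 with upper quartile scaling and 1100 and 1336 once each library was centred on its median, so this balance is not fixed either. Non-overlapping groups were seen for 42.2% of genes. Other large falls were those of Otor (log2 change -6.26), Fam60a (-4.06), Acpl2 (-3.62) and Anxa1 (-3.77), and Tmem91 rose (5.04). Hba-a1 has a near-identical copy and is uncertain. The count was 1325 and 1517 without PN libraries a and b, and 1410 and 1551 without E15.5 libraries a and c, each below the full count by over 1.5 times, where letters follow column order and carry no replicate number.

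Over the whole span from E11.5 to PN, 14 of 17 GABA and glycine receptor genes rose and 0 fell (camera adjusted p = 2.34e-07, and adjusted p = 0.170 with an estimated correlation). Of 30 synaptic vesicle and release genes 21 rose and 0 fell, 22 when adjusted over the list alone (camera adjusted p = 7.00e-07, and adjusted p = 0.0295 with an estimated correlation, so that the call held). Glutamate receptor genes had 13 of 18 up and 0 down (camera adjusted p = 4.51e-05, and adjusted p = 0.183 with an estimated correlation), and Grin1 went from 0.476 ± 0.367 to 10.5 ± 0.817 FPKM (n = 3, log2 change 3.00, SE 0.39, limma, adjusted p = 1.59e-04). Of 15 serotonin neuron transcription factors 11 fell and 1, Egr1, rose (camera adjusted p = 3.98e-05, and adjusted p = 0.183 with an estimated correlation). Gata2 was at 13.2 ± 2.46, Gata3 at 72.9 ± 4.69, Lmx1b at 3.45 ± 3.35 and Insm1 at 1.43 ± 0.506 FPKM in PN (n = 3), and Gata2 and Insm1 had the steepest falls of these 4 from E11.5 (log2 changes -3.23 and -4.43). Fev ended lower than at E11.5 (log2 change -1.92, SE 0.49, limma, adjusted p = 0.0117). Only Maob and Slc22a3 fell among the 13 synthesis and transport genes (camera adjusted p = 0.0424, and adjusted p = 0.468 with an estimated correlation), and Tph2 (limma, adjusted p = 0.0750) and Slc6a4 (limma, adjusted p = 0.231) did not pass the test.

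Across the same span camera called neuropeptides (7 of 14 up, 0 down, adjusted p = 5.74e-05, and adjusted p = 0.123 with an estimated correlation), other potassium and HCN channels (7 of 13 up, 1 down, adjusted p = 0.00274, and adjusted p = 0.129 with an estimated correlation) and other G protein coupled receptors (7 of 14 up, 1 down, adjusted p = 0.0197, and adjusted p = 0.183 with an estimated correlation). Adra1b reached 9.16 ± 1.72 FPKM in PN, and the histamine receptor Hrh3 went down from 9.69 ± 3.86 to 1.51 ± 0.364 FPKM (n = 3). Cell cycle genes were called lower (0 up, 7 down of 26, adjusted p = 0.0259, and adjusted p = 0.259 with an estimated correlation). Higher calls were also made for the lists of astrocytes (7 of 9 up, adjusted p = 7.45e-05, and adjusted p = 0.243 with an estimated correlation), microglia and blood (7 of 8 up, adjusted p = 0.00229, and adjusted p = 0.353 with an estimated correlation) and immediate early genes (8 of 13 up, adjusted p = 0.00767, and adjusted p = 0.170 with an estimated correlation). The serotonin receptors Htr5b and Htr7 rose, with Htr7 listed at 0 in the E11.5 libraries. Lists without a call were serotonin receptors, voltage-gated potassium channels, sodium and calcium channels, axon guidance and growth, neural progenitors, the oligodendrocyte lineage and mitochondrial oxidative phosphorylation, with 2, 3, 6, 10, 2, 2 and 1 genes up and 0, 1, 0, 3, 5, 0 and 0 down. Rises and falls adjusted over the list alone were 2 and 11 for serotonin neuron transcription factors, 15 and 0 for GABA and glycine receptors, 8 and 1 for other G protein coupled receptors, and 9 and 1 for other potassium and HCN channels. They were 10 and 4 for axon guidance, 4 and 6 for progenitors, 8 and 0 for astrocytes, 2 and 1 for the oligodendrocyte lineage, 9 and 1 for immediate early genes and 0 and 0 for oxidative phosphorylation. The remaining lists kept the counts given.

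The span from E11.5 to PN had 3215 changed genes by limma, 2038 higher and 1177 lower, and 2796 from the 6 libraries of those stages alone, 2753 of them in common. Requiring a mean of at least 5 FPKM, which removes weakly expressed genes from the test, left 2045. To compare the earlier with the later interval, their difference was tested for each gene: 2658 genes changed differently in them (limma), with 1129 more positive and 1529 more negative later, a balance that turned to 1314 and 1223 with upper quartile scaling. This count was 1471, 1744 and 1450 without E15.5 libraries a, b and c, which enter both intervals. The test asks whether E15.5 lies off the midpoint of E11.5 and PN. A shift of the E15.5 libraries as a set, whatever its source, cannot be told apart from a change in the neurons. Slc6a4 was among 359 genes that fell and then rose, Htr3a and Anxa1 among 569 that rose and then fell, Sst among 138 that rose in both intervals, and Gata2 among 50 that fell in both. At the same q threshold and 1.5-fold minimum, the authors' deposited table for the stages gave 2440 rises and 1947 falls for the earlier interval, and 1892 and 2027 for the later one. Genes called in one direction both there and by limma numbered 2748 and 1984, with 0 called in opposite directions. Both rest on the same libraries, so opposite calls were hardly possible. Among genes tested by both, 1550 and 1857 were called only there, and 624 and 373 only by limma.

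**Figure D1:**
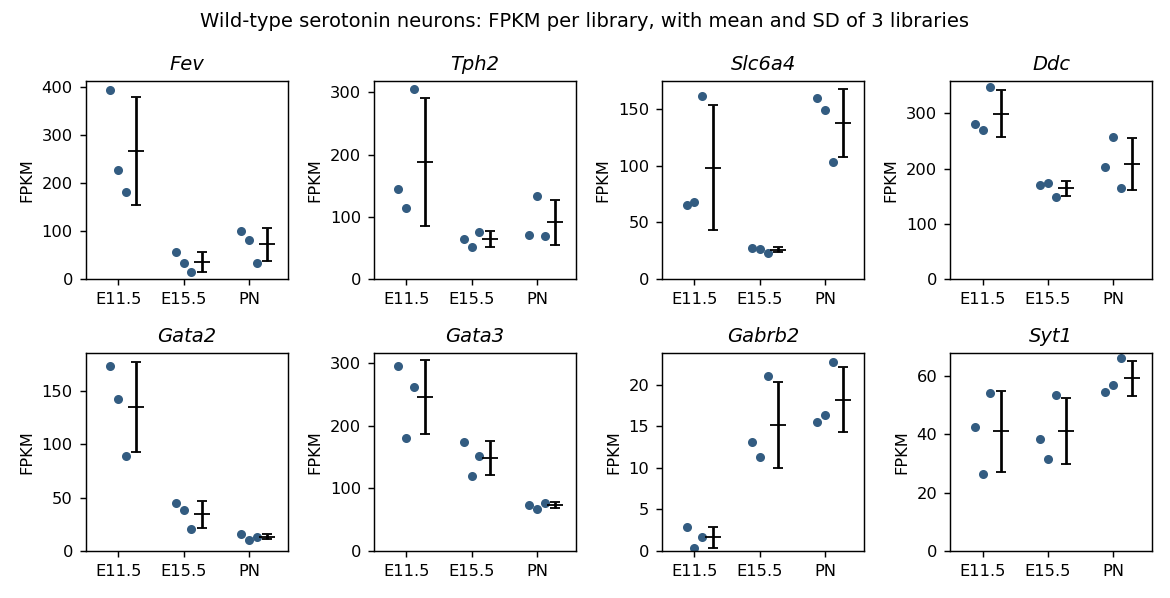
FPKM per library (vertical axes) for 8 genes at E11.5, E15.5 and PN (horizontal axes) in wild-type neurons, with points for libraries and bars for the mean and SD of 3. Fev, Tph2, Slc6a4 and Ddc sit lowest at E15.5 (35.2, 64.1, 25.9 and 164 FPKM on average), Gata2 and Gata3 are lowest in PN, Gabrb2 is lowest at E11.5, and the Syt1 libraries of E11.5 and E15.5 overlap.

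The knockout comparison asks which genes of E15.5 serotonin neurons depend on Pet-1. The targeted gene was nearly lost with both kits. In the authors' deposited table for the Clontech libraries Fev was at 31.1 FPKM in the wild type and 0.422 FPKM in the knockout (log2 change -6.20, q = 0.00391). In the authors' deposited table for the NuGEN libraries it was at 34.9 and 0.308 FPKM (log2 change -6.82, q = 0.00206). These tables hold 1 value per group from 3 libraries each and none per library, so no SD of the replicates could be given. The values of the 2 kits, normalised separately, were compared only by fold. Those q are the lowest the authors' deposited tables hold for each kit and come from a raw p of 5e-05, so genes that share them are not ranked by them.

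Without Pet-1 several genes for making, storing and taking up serotonin were lower. Tph2 fell to 9.75 from 63.5 FPKM with Clontech and to 11.1 from 218 FPKM with NuGEN in the authors' deposited tables (log2 changes -2.70 and -4.30). The authors' deposited tables gave log2 changes of -2.04 and -2.90 for Slc6a4, -1.90 and -2.39 for Ddc, -1.63 and -2.63 for Slc18a2, -2.42 and -2.10 for Gchfr, a regulator of cofactor synthesis, and -1.28 and -1.48 for Maob. Together these were 6 of the 13 synthesis and transport genes called lower in both of the authors' deposited tables, with 0 called higher, and 7 lower when adjusted over the list alone. The list held more calls than other genes (Fisher's exact test, two-sided, adjusted p = 2.12e-08). Its median of -1.38 lay below those of all 10000 random lists of the same size matched on expression in the authors' deposited tables. Among other lists over both kits, medians also lay high among matched lists for neuropeptides (percentile 99.9), serotonin receptors (99.9), sodium and calcium channels (99.2), axon guidance (99.1) and glutamate receptors (98.5). They lay low for astrocytes (0), neural progenitors (0.42), immediate early genes (0.51) and glutamate and GABA neurons (1.30), and between 9.70 and 91.9 for the remaining lists with a median. These percentiles describe the libraries at hand and are no test. Of the other members, Qdpr was called lower with Clontech alone, Gch1, Slc22a3 and Maoa with NuGEN alone, and Pts, Spr and Pcbd1 with neither, in the authors' deposited tables. All 4 genes called with 1 kit had log2 changes below 0 in both of the authors' deposited tables, for Clontech and NuGEN -1.31 and -0.50 (Qdpr), -0.58 and -1.26 (Gch1), -0.47 and -0.74 (Maoa), and -4.84 and -5.42 for Slc22a3, which had 1.21 FPKM in the Clontech wild type (q = 0.207).

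Other serotonin neuron transcription factors were mostly not called, and Fev alone was called in both kits among the 14 tested in both of the authors' deposited tables (adjusted p = 0.404, Fisher's exact test). Gata2 stood at 33.5 and 30.6 FPKM in wild type and knockout in the authors' deposited table for Clontech, and at 32.6 and 32.6 FPKM in that for NuGEN. For Gata3 the authors' deposited tables gave log2 changes of -0.26 and -0.34, and for Lmx1b 0.75 and -0.24, with q of 0.433, 0.380, 0.378 and 0.793. En1 was called lower with Clontech alone, and Sox14 lower and Nkx2-2 higher with NuGEN alone, at log2 changes of -0.92 and -0.43, -0.32 and -1.04, and 0.80 and 1.11 for Clontech and NuGEN in the authors' deposited tables. Among serotonin receptors, the autoreceptor gene Htr1a was lower with NuGEN (log2 change -2.48) and not called with Clontech (-0.21), and Htr3a and Htr7 were called higher with NuGEN alone (1.11 and 1.11, against 0.30 and 1.53 with Clontech), in the authors' deposited tables, where 0 of 4 receptors tested were called in both kits.

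Genes outside the serotonin lists lost or gained expression as well. By mean log2 change over the 2 kits in the authors' deposited tables, the largest falls called in both, outside the serotonin lists, were those of the retinaldehyde reductase Dhrs3 (-3.18), the lysophosphatidic acid receptor Lpar1 (-3.05), the proprotein convertase Pcsk5 (-3.02), Cthrc1 (-3.02), the co-chaperone Dnajc12 (-2.26) and the transcriptional coregulator Cited1 (-2.22). The largest rises by the same mean in the authors' deposited tables were those of the calcium-binding protein calretinin, Calb2 (3.56), the corticotropin-releasing hormone binding protein Crhbp (3.01), the enkephalin precursor Penk (2.82), Tac1 (2.41), the melanocortin receptor Mc4r (2.20), the transcription factor Neurod6 (1.82), Gpr153 (1.72), Zfp703 (1.61) and Frrs1 (1.49). Calb2 went from 21.6 to 240.3 FPKM with Clontech and from 22.9 to 289 FPKM with NuGEN in the authors' deposited tables. Penk went from 573 to 3095 and from 252 to 2316 FPKM in the authors' deposited tables. A pseudogene, Olfr856-ps1, also ranked among the rises of the authors' deposited tables and is uncertain.

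Neuropeptide genes held 3 calls in both kits of 11 tested in the authors' deposited tables, Penk and Tac1 higher and Pdyn lower (adjusted p = 0.00142, Fisher's exact test). Axon guidance and growth genes held 3 of 30, with the guidance ligands Slit2 and Efna5 lower and the receptor Robo2 higher, and 4 lower and 2 higher when adjusted over the list alone (adjusted p = 0.0171, Fisher's exact test on the authors' deposited tables). Of 9 other G protein coupled receptors 2 were lower in both kits in the authors' deposited tables, Lpar1 and the substance P receptor Tacr1 (adjusted p = 0.0171, Fisher's exact test). In the authors' deposited table for NuGEN alone, axon guidance genes (adjusted p = 0.528, Fisher's exact test, median at percentile 43.0 of matched lists) and other G protein coupled receptors (adjusted p = 0.0560) no longer held more calls than other genes, while both did with that for Clontech (adjusted p = 0.0408 and 0.0142). Syt1, the calcium sensor of vesicle release, was the 1 called of 29 synaptic vesicle genes (log2 changes -1.06 and -1.56 in the authors' deposited tables). Lists with 0 members called in both of the authors' deposited tables were glutamate receptors, GABA and glycine receptors, voltage-gated potassium channels, other potassium and HCN channels, sodium and calcium channels, cell cycle, Hox genes, the oligodendrocyte lineage, glutamate and GABA neurons, dopamine, noradrenaline and acetylcholine neurons, immediate early genes and mitochondrial oxidative phosphorylation. Microglia and blood, and vascular and meningeal markers, had 0 members tested in both of the authors' deposited tables. Adjusted over the list alone, the authors' deposited tables gave 2 lower and 1 higher in both kits for glutamate receptors, 2 lower each for cell cycle and neural progenitors, 3 lower for astrocytes, and 1 higher each for serotonin receptors, glutamate and GABA neurons, and dopamine, noradrenaline and acetylcholine neurons.

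Calls of progenitor and glial genes were not alike in the kits, and the difference between the kits was not tested. With Clontech 5 of 15 neural progenitor genes were lower in the knockout, 9 when adjusted over the list alone (median log2 change -1.49, adjusted p = 2.34e-04), and 5 of 8 astrocyte genes (median -2.57, adjusted p = 1.03e-05, both by Fisher's exact test on the authors' deposited table). Of 26 cell cycle genes in the authors' deposited table for Clontech, 1 was lower, Ccnd2 (named outside the rule, as are Fabp7 and Id3), and 12 when adjusted over the list alone (median -0.69). With NuGEN the authors' deposited table gave 2 progenitor genes higher, Fabp7 and Id3, and 1 lower, Vim, of 10 (median 0.62), and 1 of 7 astrocyte genes lower (median -0.54). Vim and the astrocyte transporter Slc1a3 were lower with both kits in the authors' deposited tables (mean log2 changes -1.40 and -1.89), whereas Fabp7 and Id3 were called in opposite directions. Mitochondrial oxidative phosphorylation genes had 9 of 24 higher and 1 lower with NuGEN (adjusted p = 0.00452, Fisher's exact test) and 0 called with Clontech in the authors' deposited tables, though their NuGEN median lay only at percentile 85.4 of matched lists. Ribosomal protein genes were higher in the same knockout libraries (54 of 79 called), and FPKM in the authors' deposited table for NuGEN summed to 761685 in the knockout and 563694 in the wild type, so this call cannot be parted from a difference between those libraries. Lists with more calls than other genes numbered 4 over both kits in the authors' deposited tables. They numbered 7 with the authors' deposited table for Clontech alone, where progenitors, astrocytes and immediate early genes (adjusted p = 0.0497) joined, and 4 with that for NuGEN alone, where serotonin receptors (adjusted p = 0.0430) and oxidative phosphorylation joined.

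Taking q below 0.05, at least 1.5-fold and at least 1 FPKM in a group, the authors' deposited table for Clontech gave 202 genes lower and 106 higher in the knockout of 10939, and that for NuGEN 502 and 902 of 11019. Among 10501 genes tested in both of the authors' deposited tables, 60 were lower in both, against 8.24 for independent lists (odds ratio 11.7, Fisher's exact test, two-sided, p = 3.13e-36). In the authors' deposited tables, 38 were higher in both, against 8.58 (odds ratio 6.62, p = 5.93e-16). The kits shared no library. Log2 changes in the authors' deposited tables correlated weakly across 10496 genes (Pearson r = 0.296, Spearman rho = 0.229, genes are not independent replicates), with 57.0% in the same direction. Across the 285 called with Clontech r was 0.603 and rho 0.542, with 76.1% in the same direction. Choosing genes by a large change raises such a correlation by itself, so the higher values add no evidence that the kits match. The authors' deposited tables called 9 genes in opposite directions, Anxa1, Cd63, Cenpq, Dbi, Fabp7, Fam183b, Id3 and 1810037I17Rik lower with Clontech and higher with NuGEN, and Tmem170b the reverse. All 9 lie outside the naming rule for the knockout and were named after their values were seen. At least 2-fold instead of 1.5-fold left 471 of the 1404 NuGEN calls and 55 of the 98 in both kits, and q below 0.01 left 563 and 54, with 173 of 308 for Clontech, in the authors' deposited tables.

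**Figure D2:**
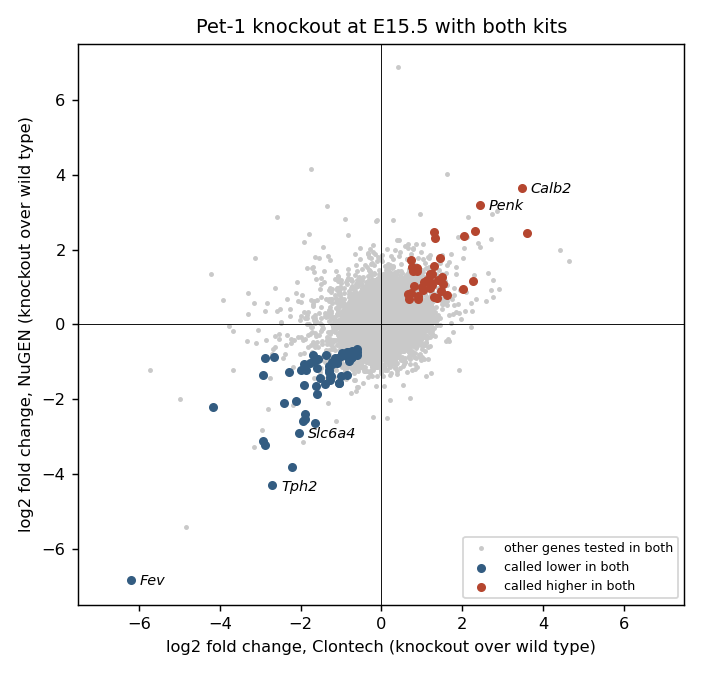
Log2 fold change of knockout over wild type at E15.5 in the authors' deposited tables, with Clontech on the horizontal and NuGEN on the vertical axis, and 1 point per gene tested in both. The 60 genes called lower in both (blue) and the 38 called higher in both (red) are set against the other genes (grey), some of which changed as much without a call in both, such as Slc22a3 at -4.84 and -5.42, with Fev at -6.20 and -6.82 and Calb2 at 3.47 and 3.66.

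Genes changed in the knockout were then placed along the wild-type stages, to ask whether Pet-1 acts on genes that rise or fall as the neurons mature. Genes higher in the NuGEN knockout rose from E11.5 to PN more often than genes not called, 205 of 876 (23.4%) against 1465 of 9294 (15.8%), by the authors' deposited table and the limma stage calls (odds ratio 1.63, Fisher's exact test, two-sided, adjusted p = 8.51e-08). Calb2, Penk, Tac1, Crhbp and Robo2 were among the 23 of 38 genes higher in both of the authors' deposited tables that rose in this span (odds ratio 8.13, adjusted p = 2.39e-09, Fisher's exact test). Genes lower in the NuGEN knockout fell over the span more often than others, 66 of 485 (13.6%) against 9.17% (odds ratio 1.56, adjusted p = 0.00237, Fisher's exact test on calls from the authors' deposited table), and Fev, Vim and Maob were examples called in both kits. For lower genes that rose the share was 13.8% (67 genes, odds ratio 0.857, adjusted p = 0.276), with the authors' deposited table for NuGEN. With the authors' deposited table for Clontech it was 29.1% (odds ratio 2.20, adjusted p = 5.70e-06). Genes higher in the NuGEN knockout by the authors' deposited table also fell more often, 131 of 876 (odds ratio 1.74, adjusted p = 3.35e-07). The authors' deposited table for Clontech gave 4 of 102 (odds ratio 0.374, adjusted p = 0.0435), so both of these odds ratios lay on opposite sides of 1 in the kits, a difference that was not tested. From E11.5 to E15.5 alone, with the authors' deposited table for NuGEN, lower genes were not linked to falls nor higher genes to rises past the threshold (odds ratios 0.847 and 0.900, adjusted p = 0.361 for both, Fisher's exact test). In that interval lower genes rose more often than others (odds ratio 1.82, adjusted p = 1.15e-07) and higher genes fell more often (odds ratio 1.49, adjusted p = 2.24e-04, Fisher's exact test on calls from the authors' deposited table). From E15.5 to PN, with the same table, lower genes fell in 112 of 485 (23.1%) against 9.65% of others. Higher genes rose in 16.4% against 8.80%. The odds ratios were 2.81 and 2.04 (Fisher's exact test, adjusted p = 2.16e-16 and 1.61e-11). Lower genes rose less often (odds ratio 0.611, adjusted p = 0.0168), while higher genes that fell did not pass the test (odds ratio 0.902, adjusted p = 0.435, Fisher's exact test). Across these intervals lower genes thus rose and then fell, and higher genes fell and then rose, more often than others. Both intervals share the E15.5 libraries, so a shift of those libraries as a set cannot be told apart from a link to maturation. The other genes were not matched on expression.

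The chromatin data ask where tagged Pet-1 was bound in embryonic hindbrain. The authors' list held 4934 peaks on 21 chromosomes of mouse build mm10, called from 1 immunoprecipitation against 1 input with no replicate, with a median width of 885 bp and the authors' scores from 50 to 3133. The labels give conflicting ages and genotypes for this sample, wild type in one field and a Pet-1 knockout carrying the tagged transgene in another. The highest-scoring peak lay at Supv3l1, which encodes a mitochondrial helicase, on chromosome 10 at 62449086 to 62450610 (score 3133.01). The next 4, all with a score of 3100, lay at Cdk12 (chromosome 11, 98202080 to 98203398), Qrich1 (chromosome 9, 108516444 to 108517523), Denr (chromosome 5, 123906683 to 123908135) and Mdh2 (chromosome 5, 135778065 to 135779368). Each overlapped the gene named in RefSeq's GRCm38.p6 gene spans, which give no strand, exon or promoter. The peaks at Supv3l1, Cdk12 and Mdh2 also overlapped 4930507D05Rik, Gm38963 and Styxl1, in that order (named outside the rule). Which gene of such a pair a peak belongs to is not known. Equal scores were ordered by start position, so the 4 peaks at 3100 are not ranked among themselves. Whether further peaks share that score was not examined.

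A peak with a score of 59.9 covered one end of Fev itself, on chromosome 1 at 74885425 to 74887312. That peak was also the one near Cryba2, which was lower in both knockout tables and was named after its values were seen. Among serotonin synthesis and transport genes Gchfr alone had a peak within 5 kb of either end (chromosome 2, 119167188 to 119167907 and 119171636 to 119172235, scores 69.9 and 55.2). Tph2, Slc6a4 and Ddc had none there. Among transcription factor genes, En1 had its highest-scoring peak at 120603283 to 120606055 on chromosome 1 (score 621), En2 at 28166051 to 28167381 on chromosome 5 (417), and Lmx1b at 33638466 to 33640056 on chromosome 2 (299). For Gata2 it lay at 88193503 to 88195485 on chromosome 6 (297), for Hmx2 at 131554311 to 131556578 on chromosome 7 (377) and for Pou3f2 at 22486601 to 22488353 on chromosome 4 (207). Hmx3, Nkx2-2, Foxa2, Insm1, Sox14, Egr1 and the receptor gene Htr1b had peaks as well, with scores between 58.1 and 312.

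Genes changed in the knockout had peaks less often than other genes. Of the 60 genes lower in both of the authors' deposited tables, 10 (16.7%) had a peak within 5 kb of either end, against 4081 of 10323 (39.5%) not called in one direction by both kits (odds ratio 0.306, Fisher's exact test, two-sided, p = 1.74e-04, adjusted p = 1.74e-04). Of the 37 matched genes higher in both of the authors' deposited tables, 4 (10.8%) had one, Meis2, Rpp25, Runx1t1 and Zfp703 (odds ratio 0.185, p = 1.58e-04, adjusted p = 1.74e-04, Fisher's exact test). Of these only Zfp703 fell under the naming rule, and the others were named after their values were seen. Among 10000 random sets matched on wild-type FPKM, 99.99% and 100% held at least as many genes with a peak. With the authors' deposited table for NuGEN alone the difference did not pass the test, at 35.4% of 500 lower genes (odds ratio 0.866, adjusted p = 0.288) and 38.9% of 893 higher genes (odds ratio 1.00, adjusted p = 0.943). A peak near a gene does not show that the gene is bound as a target, and a distal site would be missed.

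**Figure D3:**
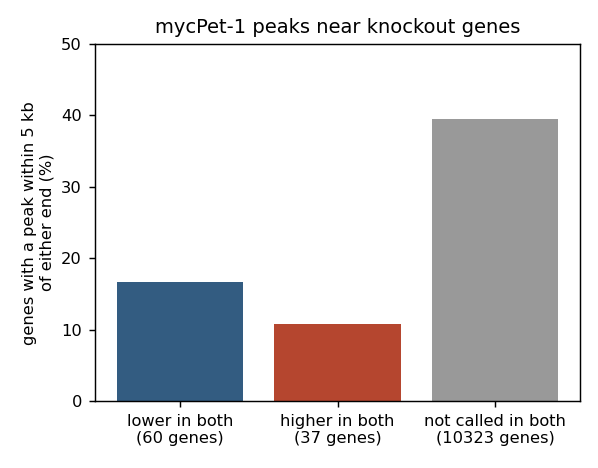
Share of genes (vertical axis, percent) with a tagged Pet-1 peak within 5 kb of either gene end, for genes lower in both knockout tables, higher in both, and not called in one direction by both (horizontal axis, with gene numbers). The bars stand at 16.7%, 10.8% and 39.5%, and each is a share of genes with no replicate error.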

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

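The alternatives were fixed before the data were examined, apart from 6 added after seeing the data: the E11.5 and PN libraries alone, list tests with upper quartile scaling, with a pseudocount of 0.1 and without each library, the knockout link to the E11.5 to E15.5 interval, and peaks over gene bodies. Of 119 values that answer a comparison under an alternative, 91 kept their direction and side of the threshold, or stayed within 1.5 times for a count, 17 counts moved by over 1.5 times, 9 odds ratios reversed, 1 weakened past its threshold and 1 passed it. Of 5924 values for named genes under an alternative, 5570 stayed called or stayed uncalled, 315 lost a call, 39 gained one and 0 reversed. Genes never called count among the 5570, so it is not a number of calls kept. Knockout log2 changes are the same under every threshold, so none of those could reverse. Unless a reason is given here, the cause was not tested. Depth is unknown, so its limit on weakly expressed genes could not be given.

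The E11.5 to PN count was 2045 with a mean FPKM of at least 5, where fewer genes were tested, and the E15.5 to PN count was 3919 by the q of the authors' deposited table, which rests on another test. Leaving out 1 library at a time, the counts ranged from 2383 to 3315 for E11.5 to E15.5, from 1325 to 2960 for E15.5 to PN, from 2437 to 3134 for E11.5 to PN, from 1450 to 2824 for the difference of the intervals and from 24 to 31 for the lists. The E15.5 to PN count fell to 1410, 1551, 1325 and 1517 without E15.5 libraries a and c and PN libraries a and b, and that of the difference to 1471, 1744 and 1450 without E15.5 libraries a, b and c. Each leaves 1 library fewer to estimate the spread. Of 69 list tests, camera with an estimated correlation called 2 and fry, which does not compare a list with other genes, called 45, against 29 with camera's preset correlation.

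For the knockout, q below 0.01 left 173 Clontech calls, 563 NuGEN calls and 54 calls in both kits, and at least 2-fold left 471 NuGEN calls and 55 in both. Stricter thresholds can only lower these counts. With the Clontech table alone 7 lists were called, against 4. With NuGEN alone 4 were called, without axon guidance and other G protein coupled receptors. For genes lower in the knockout that rose along the stages, the odds ratio was 2.20 with the Clontech table, 1.77 for genes called in both kits, 1.82 for E11.5 to E15.5 and 0.611 for E15.5 to PN, the last now past the threshold, against 0.857. For lower genes that fell it was 0.847 for E11.5 to E15.5, and for higher genes that rose 0.900. For higher genes that fell it was 0.374 with Clontech, 0.247 in both kits and 0.902 for E15.5 to PN. Peaks near genes called with NuGEN alone gave 0.866 for lower genes, no longer past the threshold, and 1.00 for higher genes, just above 1.

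No paired analysis was possible because the columns of the stage matrix carry no replicate number from the labels and the knockout tables hold no value per library. The replicate block was therefore not run, nor was a q of the authors for E11.5 to PN, which the table used here does not compare. The ETS motif in peaks and its alternatives were not run, since no genome sequence was used here.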

Other observations

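Of 24 genes of mitochondrial oxidative phosphorylation, 6 rose, 5 fell and 13 were not called from E11.5 to E15.5, and camera called no direction (adjusted p = 0.954). Among all 11741 genes tested, 2046 rose and 1348 fell, so single members are described here and no pattern of the list. The succinate dehydrogenase genes Sdha and Sdhd were highest at E15.5, with log2 changes of 1.58 and then -1.44 for Sdha. Sdhd was at 19.1 ± 5.96, 132 ± 54.2 and 30.4 ± 4.89 FPKM at E11.5, E15.5 and PN (n = 3). Each rise and fall passed the test (limma, adjusted p = 9.36e-04 and 0.00274 for Sdha, 2.54e-04 and 0.00269 for Sdhd). Uqcrfs1, a complex III subunit, went the other way, at 370.1 ± 38.9, 111 ± 33.9 and 369.9 ± 84.8 FPKM (n = 3, limma, adjusted p = 8.94e-04 and 0.00171). The cytochrome oxidase genes Cox5a and Cox5b likewise fell by 0.99 and 1.36 (log2) and then rose by 1.15 and 1.05 (limma). Other genes were highest at E15.5 too, 569 by a called rise and a called fall. Of these, Anxa1 was at 0.00657 ± 0.0114, 52.7 ± 28.2 and 2.91 ± 2.09 FPKM, and Gpx8 at 0.0132 ± 0.0228, 43.4 ± 15.9 and 7.94 ± 2.01 FPKM (n = 3 each). Otor was at 20.8 ± 4.33, 116 ± 42.8 and 0.649 ± 1.07 FPKM (n = 3). A shift of the E15.5 libraries as a set cannot be told apart from such courses in the neurons.

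The tests below on Fev, Slc6a4, Tph2, other cells in either kit and expression level beside peaks, and the counts of other splits, were chosen after the results were seen. The tests of ribosomal protein genes, of 2-fold changes and of peaks along the stages were set before their own values were computed, though after the patterns they bear on had been seen. Splits of the libraries tested whether chance could give the counts of changed genes. For E11.5 to E15.5, E15.5 to PN and E11.5 to PN, 1 of 10 splits of the 6 libraries gave as many genes, the real one (3394, 2370 and 3215 genes, against at most 1, 1 and 4 in the others). For the lists, adjusted here over the 23 of a comparison, 2, 3 and 1 of 10 splits gave as many calls, with 5, 9 and 12 in the real split and at most 6, 9 and 10 in the others. Over 69 tests 8 lists were called from E11.5 to E15.5, and those of synaptic release, other potassium and HCN channels and neuropeptides were lost over 23. With 10 splits no share under 0.05 can be reached. For the difference between the intervals 1 of 100 splits gave as many genes, the real one (2658, against at most 2057). The other splits mix libraries of different stages, which widens the spread within groups and favours the real split. This count therefore cannot exclude chance for the difference.

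Fev, Slc6a4 and Tph2 were lower at E15.5 than at E11.5, while astrocyte genes such as Slc1a3 were higher, so RNA of other cells in the sort might have diluted that of serotonin neurons. Dilution lowers all genes of these neurons alike, and Fev fell beyond Ddc by a log2 difference of -2.13 (SE 0.63). This argues against dilution as the whole cause for Fev only if Ddc comes from the same neurons, which was not tested. Other cells that held Ddc RNA would make its fall smaller, and the comparison could then not decide. Slc6a4 fell beyond Ddc by -0.90 (SE 0.31), but its log2 change of -1.76 (SE 0.35) lay near that of Tph2, -1.43 (SE 0.38). For Slc6a4 the answer thus depends on the reference gene, and dilution stays open. Th, a marker of other neurons, also rose in this interval. For Tph2 the difference from Ddc was -0.57 (SE 0.39), where dilution cannot be told apart from a change in the neurons, and for Slc18a2, whose joint test with Tph2 and Slc6a4 was replaced by single ones after its result was seen, it was 0.32 (SE 0.42), which dilution allows. Upper quartile scaling left the log2 change of Fev at -3.17. The upper quartiles of the 9 libraries spanned only 21.9 to 27.3 FPKM, so this rescaling could not have removed such a fall. Scaling differences of that size do not account for it, and no other scaling is given here for Fev. A fall in the neurons between these ages stays open as a hypothesis. Differences in which neurons were sorted at each age, which the labels do not record, stay open too, as does a shift of the E15.5 libraries as a set.

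The kits differed in 2 ways: the median change of progenitor genes was -1.49 in the Clontech and 0.62 in the NuGEN knockout, and NuGEN gave 1404 calls against 308. For Clontech, the highest of the 4 medians of progenitor, astrocyte, cell cycle and oligodendrocyte lists was -0.37, which is consistent with fewer other cells in the knockout than in the wild-type libraries, with Vim at 64.2 and 18.9, Slc1a3 at 16.1 and 2.18 and, named outside the rule, Apoe at 14.7 and 1.15 FPKM in wild type and knockout in the authors' deposited table, although the sort for EYFP should remove such cells. For NuGEN the lowest of the same medians was -0.54, for astrocytes, against more other cells of all kinds in the knockout, although Fabp7 and Id3 were higher. Ribosomal protein genes, which are short and have many pseudogenes, lay 0.70 (log2) above all genes with NuGEN, 54 of 79 called higher against 0 with Clontech, so uneven recovery of short transcripts is a candidate cause of part of the excess. A smaller spread between NuGEN libraries stays open, because 342 genes with at least 5 FPKM changed by 2-fold whatever their q against 237 with Clontech, a ratio of 1.44, and the tables hold no value per library; an effect of Pet-1 on these genes was not tested apart from the kit.

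Genes changed in both knockout tables had a peak of tagged Pet-1 nearby less often than other genes, which did not pass the test for lower or higher genes by the NuGEN table alone (odds ratios 0.866 and 1.00). Expression level is argued against as the cause, since 99.99% of random sets matched on wild-type FPKM held at least as many genes with a peak as the lowered genes. Genes that changed from E11.5 to PN in wild type, another comparison, also had a peak less often (998 of 3196 against 3374 of 8443, odds ratio 0.682, Fisher's exact test, p = 2.37e-18), so a candidate explanation is that peaks within 5 kb lie mostly at steadily expressed genes, which seldom pass a fold threshold in any comparison. This odds ratio lay nearer 1 than those of 0.306 and 0.185 for the knockout genes, and that difference was not tested. Binding away from gene ends, unspecific signal at open promoters in a single immunoprecipitation, and effects of Pet-1 through other factors remain open and untested.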
